A study of Mus musculus with 6 samples.

How the data were processed

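RNA was measured by sequencing in 6 libraries of mouse embryonic stem (ES) cells. The libraries fall into 3 groups of 2: a control clone with floxed alleles of Cbx5 (HP1 alpha) and Cbx1 (HP1 beta), and clones 1 and 2 of the double knockout (DKO) of both genes. The labels give the control genotype as wild type. HP1 proteins bind methylated lysine 9 of histone H3 in heterochromatin. All cells were grown in DMEM with knockout serum replacement, leukaemia inhibitory factor and a pair of inhibitors, 3 µM CHIR99021 against GSK3 and 0.8 µM PD184352 against MEK. RNA was purified on RNeasy columns and treated with Turbo DNase, and libraries were made with the stranded ScriptSeq v2 kit. The labels do not say whether the libraries of a clone came from separate cultures.

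The authors aligned the reads with STAR 2.5.0a to mm10 (GRCm38), and the deposited values are raw read counts per Entrez gene, with a gene width beside them. The counting tool, the annotation release, the strand that was counted, the handling of reads that match several genes and the floxed exons are not given in the sources used here. A count for Cbx5 or Cbx1 may therefore also cover exons outside the deleted part. Of 24467 gene IDs, 24437 were matched to a reference gene table on the same build, which gave symbols, biotypes and positions. The 30 unmatched IDs took 0.389 to 1.62% of the reads of a library. The values were checked to be whole numbers, and the replicates of a group were checked not to be parts of 1 library. The chi-square per gene between them was 49.4 in the control, 13.4 in clone 1 and 14.2 in clone 2, against 1 expected where 1 library is split. Among the unmatched IDs, 1 took 1.60% of the reads in control replicate 1 and 0.46% in control replicate 2.

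Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr with the 3 groups left 14771 genes, and libraries were scaled by TMM, with factors between 0.992 and 1.01. Expression is given as CPM from the cpm function of edgeR, scaled by TMM, and where no SD is given the value is the mean of the 2 or 4 libraries of a group. Changes were tested with the edgeR quasi-likelihood F test, which is two-sided, and p-values were adjusted by Benjamini and Hochberg (BH) with a threshold of 0.05. DKO against control used a fit with genotype as the only term, 4 DKO against 2 control libraries and 4 residual degrees of freedom. Each clone against control, and clone 2 against clone 1, used a fit with 3 groups and 3 residual degrees of freedom. The last of these contrasts is also the test of whether the effects of the clones against the shared control differ. Standard errors (SE) of log2 changes were taken from the F statistic. These p-values measure the spread between the 6 libraries only, which may be technical, and with 1 control clone a difference between genotypes cannot be told apart from a difference between clones.

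Gene lists, 23 of named symbols and 15 families, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. BH adjustment ran over the 34 lists that had 5 or more tested members. Members of a list were counted as called over all genes and adjusted over the list alone. The HP1 family, with 3 tested genes, and the alpha and beta protocadherins, with 1 and 2, were too small for the test, and mitochondrially encoded genes were not analysed here. Genes called in both clone contrasts were counted and set beside the count from independent lists and beside 20 simulated draws in which unchanged groups shared the control libraries. For each chromosome the median log2 change was taken relative to the median of all tested genes, and regions were examined in bins of 10 Mb with at least 10 genes.

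Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Cbx5, Cbx1 and Cbx3, and the 12 genes per direction with the largest change in DKO against control among those called in the genotype fit and, with the same sign, in both clone contrasts, at an average of 2 CPM or more. It also names 6 genes per direction between the clones, and up to 4 members of each list with the smallest adjusted p. The text gives the values of part of these genes, and the other genes it names were chosen after their values were seen, which is stated where it applies. Results for 2 genes that the rule names are not reported here. Alternatives were other scaling (RLE, library size), other filters, DESeq2 1.42.0, limma-voom, each clone alone, counts summed per clone, a replicate block and leaving out each library in turn. Fits without chromosomes 3, 6 and Y and fits with each chromosome centred on its own median were added after the data were seen. The fits were tested on simulated data with 200 of 14771 genes changed. In DKO against control, 68% of 1.5-fold and 86% of 2-fold changes were recovered, and 10.8% of the calls were false, above the nominal 5%. The simulated DKO libraries held no difference between clones, while the real genotype fit has that difference in its residual spread. These shares may therefore not describe the real comparison of DKO with control. The share of false calls was 9.34% for clone 1, 8.62% for clone 2 and 7.82% between the clones. Intervals at 95% are exact (Clopper-Pearson) and cover counting error only.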

Results

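The series measured messenger and other RNA in ES cells that had lost HP1 alpha and HP1 beta, in 2 deleted clones and 1 control clone with 2 libraries each. The control libraries held 34641560 and 32327537 counted reads, those of clone 1 held 27876620 and 27822664, and those of clone 2 held 24628872 and 26772203. Between 17482 and 18174 genes had at least 1 read in a library, and the 10 most abundant genes took 4.78 to 7.28% of the reads. The first principal component carried 38.9% of the variance and the second 24.9%.

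The first question was whether the targeted genes had lost expression. Cbx5, which codes for HP1 alpha (Entrez 12419, GRCm38 chromosome 15, 103191546 to 103239904), fell from 811 ± 2.96 CPM (SD, n = 2) in the control to 198 ± 6.58 CPM (SD, n = 4) in the DKO libraries, 24.4% of the control. Cbx1, which codes for HP1 beta (Entrez 12412, chromosome 11, 96788680 to 96808982), fell from 225 ± 2.88 to 45.7 ± 2.44 CPM, 20.3% of the control. The log2 changes were -2.04 (SE 0.058) and -2.30 (SE 0.0675), both with adjusted p = 3.9e-08. The 2 clones held 200 and 196 CPM of Cbx5 and 46.6 and 44.7 CPM of Cbx1, and the test of their difference gave adjusted p = 0.847 and 0.725. Cbx3, which codes for HP1 gamma (Entrez 12417, chromosome 6, 51470154 to 51483704), rose from 332 ± 16.4 to 462 ± 19.04 CPM, a log2 change of 0.48 (SE 0.0665, adjusted p = 0.0021). Without control replicate 1 its adjusted p was 0.0582, and with each chromosome centred on its own median its log2 change was 0.0030 (adjusted p = 0.986).

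**Figure D1:**
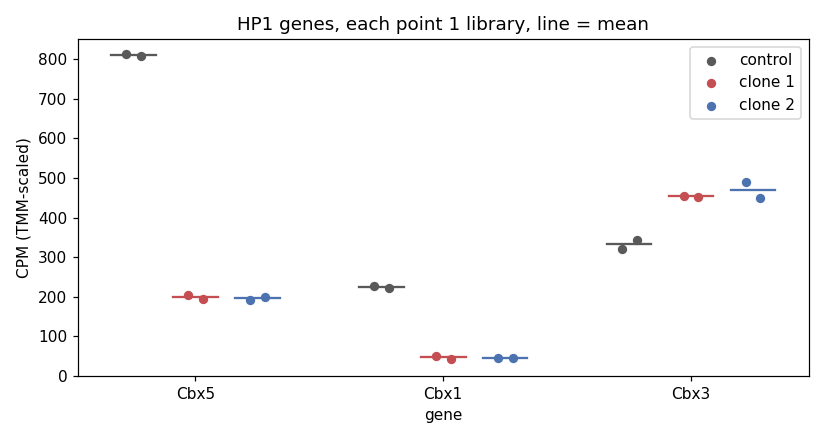
Expression of the HP1 genes Cbx5, Cbx1 and Cbx3 in CPM (vertical axis) in the control and both DKO clones, where each point is 1 library and each line the mean of 2. Cbx5 stood at 811 CPM in the control and 198 CPM over the DKO libraries, Cbx1 at 225 and 45.7 CPM, and Cbx3 at 332 and 462 CPM.

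Genes of chromosome 6 were higher as a block in both clones. The median log2 shift of its 709 tested genes was 0.44 in clone 1 and 0.51 in clone 2, 1.36 and 1.43 times the control, and all 15 of its bins lay above 0 in each clone. Chromosome 3 (701 genes) was shifted by 0.29 in clone 1 and by 0.08 in clone 2. The part of chromosome 14 from 40 Mb (353 genes) was shifted by -0.03 in clone 1 and -0.20 in clone 2. This limit was not fixed beforehand, and the whole of chromosome 14 was shifted by -0.04 in clone 1 and -0.14 in clone 2. The 10 tested genes of the Y chromosome had medians of 0.34 and 0.52, with single libraries from 0.16 to 0.72 and the control libraries 0.12 apart. The other 17 chromosomes lay between -0.07 and 0.06 in clone 1 and between -0.04 and 0.06 in clone 2, where the control libraries differed from each other by -0.02 to 0.02. For scale, 3 copies against 2 would give 0.585. These shifts are descriptions across genes with no p-value, since genes of a chromosome are not independent replicates.

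**Figure D2:**
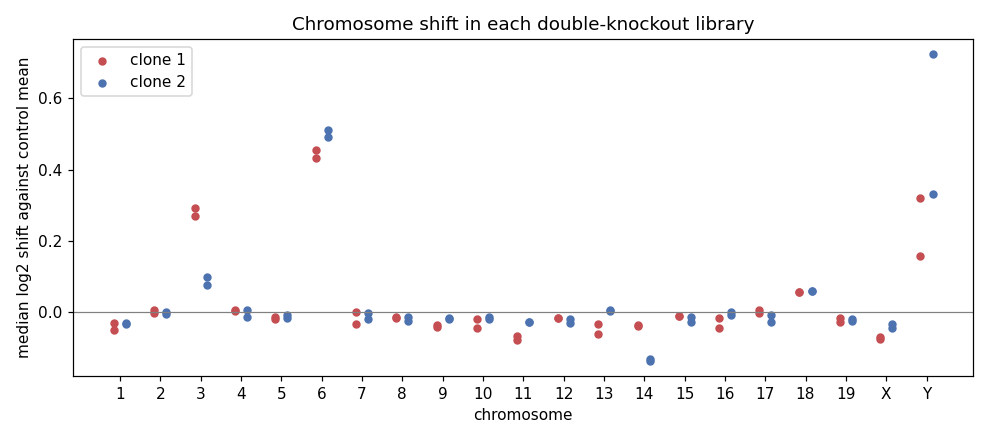
Median log2 shift of the genes of each chromosome (horizontal axis) in each DKO library against the control mean (vertical axis, log2), where each point is 1 library. The 4 DKO libraries lie between 0.43 and 0.51 on chromosome 6, and chromosome 3 is shifted by 0.29 in clone 1 and 0.08 in clone 2.

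**Figure D3:**
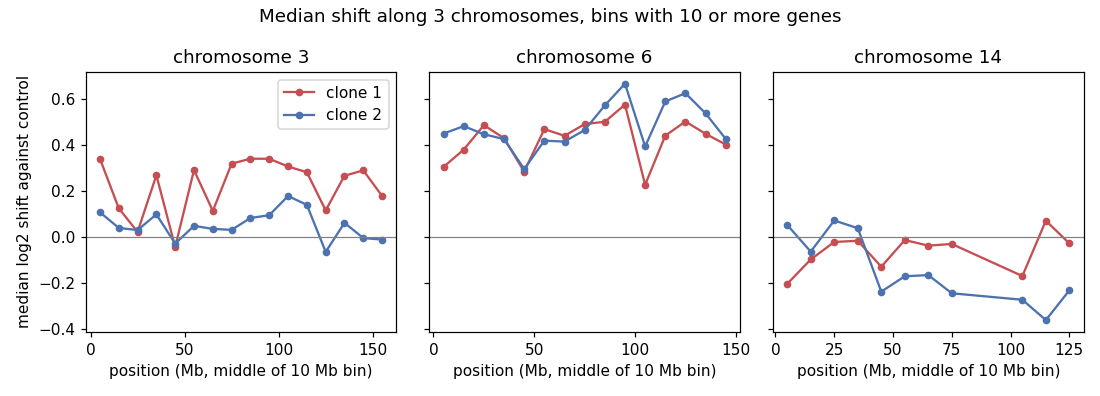
Median log2 change against control (vertical axis) in bins of 10 Mb with at least 10 genes along chromosomes 3, 6 and 14 (horizontal axis, position in Mb) in both clones. On chromosome 6 all 15 bins lie between 0.23 and 0.57 in clone 1 and between 0.30 and 0.67 in clone 2.

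The main comparison asked which genes changed when HP1 alpha and HP1 beta were both missing. Selenoi, an enzyme of phosphatidylethanolamine synthesis, rose from 9.10 ± 0.641 to 43.4 ± 5.56 CPM (SD, n = 2 and 4; log2 change 2.25, adjusted p = 3.7e-05). Nrp2, a receptor for semaphorins and VEGF, rose from 17.6 ± 1.33 to 59.5 ± 10.7 CPM, and Col6a3, a chain of collagen VI, from 1.67 ± 0.0331 to 8.0 ± 1.80 CPM. Trh, the precursor of thyrotropin-releasing hormone, lies on chromosome 6 and rose from 135 ± 8.78 to 426 ± 101 CPM, a log2 change of 1.65 that was 1.18 after centring. Among the genes that fell, the ubiquitin-specific protease gene Usp26 on the X chromosome went from 14.7 ± 0.262 to 1.66 ± 1.09 CPM (log2 change -3.15, SE 0.398, adjusted p = 0.0014). Anxa1, an annexin, fell from 9.04 ± 1.17 to 1.84 ± 0.639 CPM, and Bglap3, an osteocalcin-related gene, from 54.7 ± 6.75 to 15.8 ± 5.24 CPM. The largest rise named by the rule was that of Fstl5 on chromosome 3, from 0.312 ± 0.135 to 5.87 ± 5.03 CPM (log2 change 4.21, adjusted p = 0.0283), with 10.2 CPM in clone 1 and 1.53 in clone 2. Its adjusted p was 0.207 without control replicate 1 and 0.238 without control replicate 2.

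In DKO against control 748 genes rose and 535 fell, so 58.3% of the called genes were higher. Chromosome 6 held 46.5% of the genes that rose but 4.80% of the tested genes, and chromosome 3 held 12.03%. Outside chromosomes 3, 6 and Y, 305 genes rose and 510 fell, so 37.4% were higher, and with each chromosome centred 335 rose and 451 fell. Changes of at least 2-fold were called for 83 genes that rose and 180 that fell. Without control replicate 1 the counts were 158 and 88, without control replicate 2 they were 210 and 103, and with counts summed per clone, which leaves 1 residual degree of freedom, only Cbx5 and Cbx1 passed in edgeR (883 genes higher and 742 lower at unadjusted p under 0.05). Of 114 named calls, 77 ended without control replicate 1 (adjusted p 0.0507 to 0.365) and 61 without control replicate 2 (0.0501 to 0.338), while between 8 and 17 ended without 1 of the DKO libraries.

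Genes of the 2-cell embryo, which ES cultures express in a small share of cells, were lower in both clones. Of 41 tested 2-cell-like genes 24 fell, 1 rose and 16 did not pass, with a median log2 change of -1.17. Adjusted over the list alone, 26 fell and 1 rose. Zscan4a, a telomere-associated zinc finger gene, fell from 23.8 ± 0.260 to 8.90 ± 1.48 CPM (SD, n = 2 and 4; adjusted p = 7.7e-04), Zscan4f from 27.4 to 9.71 CPM and Zscan4d from 19.8 to 6.92 CPM. The gene that rose, the ribosomal protein-like Rpl39l, went from 20.9 to 44.6 CPM (adjusted p = 0.0232, but 0.225 and 0.156 without control replicate 1 and 2). In the Oosp, Obox and Pramel families of oocyte and early embryo genes 14 of 20 tested members fell and the other 6 did not pass, with a median of -1.29, and 17 fell adjusted over the list alone. Pramel7 fell from 66.6 to 35.4 CPM and Pramel24 from 3.14 to 0.821 CPM. The list test gave adjusted p = 1.4e-29 for the 2-cell-like list, but adjusted p = 0.12 with an estimated correlation. For the Oosp, Obox and Pramel families it gave 5.5e-18, and adjusted p = 0.0412 with an estimated correlation, which no other list passed in this comparison. Copies of Zscan4, Usp17l and Pramel genes are near-identical, so the assignment of reads to 1 copy is uncertain.

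**Figure D4:**
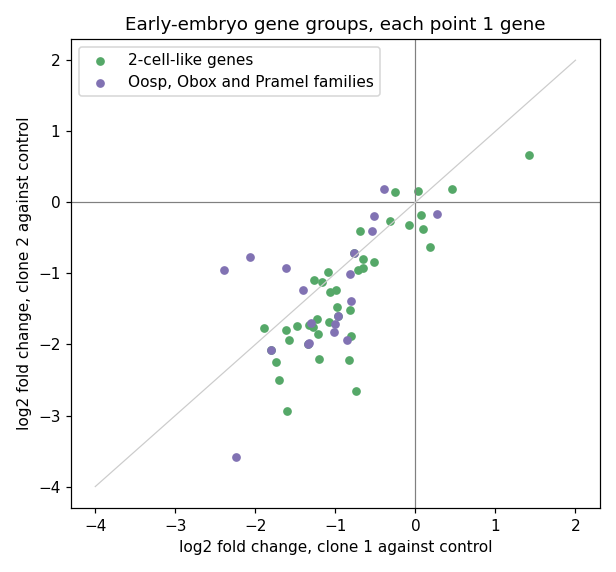
Log2 change against control in clone 1 (horizontal axis) and clone 2 (vertical axis), where each point is 1 gene of the 2-cell-like list or of the Oosp, Obox and Pramel families. Most points lie below 0 in both clones, and the medians of the 2-cell-like list are -0.98 and -1.48.

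Germline genes were lower as a group: 12 of 71 fell and the other 59 did not pass, with a median log2 change of -0.34, while 20 fell and 3 rose adjusted over the list alone. Sycp1, a component of the synaptonemal complex, fell from 24.2 to 8.90 CPM, Ddx4, a helicase of germ cells, from 17.4 to 8.67 CPM, and Tex15 from 112 to 64.1 CPM. The list passed with adjusted p = 1.3e-07, but not at adjusted p = 0.12 with an estimated correlation. Of the X-linked Rhox cluster 2 of 7 genes fell, also adjusted over the list alone (median -0.51, adjusted p = 0.0219, adjusted p = 0.377 with an estimated correlation). Of the Xlr and Slx families 2 of 12 fell, or 4 adjusted over the list alone (median -0.12, adjusted p = 0.0219, adjusted p = 0.298 with an estimated correlation), and reads of these copies are also uncertain. Markers of fibroblasts and feeder cells, a check for another cell type, had 3 of 17 genes lower and 1 higher, or 7 and 1 adjusted over the list alone. Their median was -0.28, with adjusted p = 0.0069, and adjusted p = 0.298 with an estimated correlation. Acta2, smooth muscle actin, fell from 6.02 ± 1.26 to 1.60 ± 0.752 CPM (SD, n = 2 and 4), with adjusted p = 0.0063, 0.0555 without control replicate 1 and 0.109 without control replicate 2. Without control replicate 2 the list tests gave 0.0754 for Rhox, 0.0594 for Xlr and Slx and 0.0754 for the fibroblast markers. The Rhox median was -0.83 without control replicate 1 and -0.84 without clone 2 replicate 1, and the fibroblast median was -0.18 without clone 1 replicate 1 and -0.15 without control replicate 2, but -0.47 outside chromosomes 3, 6 and Y and -0.48 without a filter on low counts. With chromosomes centred the Xlr and Slx test gave 0.0651, and 2 calls ended: the log2 change was 1.05 and then 0.58 for the fibroblast marker Fbln2, and -0.43 and then -0.38 (adjusted p = 0.0997) for Rhox5, about as large as before.

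The 3 lists that passed as higher each held few called genes. Of 67 replication-dependent histone genes 9 rose and 1 fell, or 10 and 1 adjusted over the list alone, with a median of 0.20. H3c14 rose from 258 to 369 CPM, H2ac18 from 481 to 685 CPM and H2ac20 from 186 to 273 CPM, all on chromosome 3. These calls were kept after centring, with log2 changes of 0.52 (then 0.335), 0.51 (then 0.33) and 0.55 (then 0.37). Outside chromosomes 3, 6 and Y the counts were 2 and 1 of 57. There the list test gave adjusted p = 0.0016 (median 0.16), and with chromosomes centred 3.7e-05 (median 0.22). With an estimated correlation no list passed as higher in either setting. In the list of glycolysis and hypoxia genes 4 of 28 rose and the other 24 did not pass, and 6 rose adjusted over the list alone, with a median of 0.10. The glucose transporter gene Slc2a3 on chromosome 6 rose from 486 ± 39.0 to 1188.13 ± 59.8 CPM (SD, n = 2 and 4), a log2 change of 1.29 that was 0.82 after centring (adjusted p = 4.9e-04). None of the 22 gamma protocadherin genes passed in edgeR, over all genes or adjusted over the list alone, nor in DESeq2 or limma-voom. At unadjusted p under 0.05, 9 of them were higher, and the shared exons of this cluster make their counts alike. The list tests gave adjusted p = 2.2e-04 for histones, 0.0090 for glycolysis and hypoxia and 5.7e-04 for the gamma protocadherins. With an estimated correlation they gave adjusted p = 0.618, 0.638 and 0.712. Against control, the histone median was 0.06 in clone 1 (list adjusted p = 0.0797) and 0.30 in clone 2 (list adjusted p = 5.1e-07). The glycolysis median was -0.0012 in clone 1 (list adjusted p = 0.375) and 0.24 in clone 2 (list adjusted p = 4.4e-05). For clone 2, each of these lists had adjusted p = 0.419 with an estimated correlation. Centring ended the calls of Gapdh (log2 change 0.57, then 0.09), Hk2 (0.35, then -0.13) and H2bc18 (0.45, then 0.27). The glycolysis list gave 0.232 outside chromosomes 3, 6 and Y, 0.0545 with chromosomes centred and 0.101 without clone 2 replicate 1. Its median was 0.15 without clone 1 replicate 2 and 0.042 without clone 2 replicate 1, and that of the histone genes was 0.13 without clone 2 replicate 2.

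Lists of the chromatin machinery and of pluripotency did not pass, and part of the calls on their members were on chromosomes 3 and 6. Among pluripotency and formative genes named by the rule, Jam2, Nr5a2, Cdh2 and Zic2 kept their calls after centring. Among imprinted ones Snrpn, Snurf, Impact, Atp10a, Igf2r, Ddc and Peg10 kept theirs. Each of these pluripotency, formative and imprinted calls ended, however, without at least 1 of the control libraries. Without clone 1 replicate 1 the adjusted p was 0.0555 for Nr5a2, 0.0870 for Zic2, 0.0521 for Igf2r and 0.0811 for Ddc. Without clone 1 replicate 2 it was 0.0531 for Cdh2. The calls of Jam2, Snrpn, Snurf, Impact, Atp10a and Peg10 did not end without any 1 DKO library. The log2 change of Peg10 on chromosome 6 went from -0.41 to -0.89. Among chromatin genes the kept calls were those of Mbd1 (log2 change 0.61, then 0.55), Zfp57 (-0.40, then again -0.40), Epop (0.48, then 0.53) and Yaf2 (-0.75, then -0.74). Without control replicate 1 their adjusted p was 0.0622, 0.183, 0.0785 and 0.0525, and without control replicate 2 it was 0.0501 for Epop and 0.0897 for Yaf2. In the H3K9 methylation and HP1 partner list 4 of 43 genes rose and 2 fell, and 4 rose and 4 fell adjusted over the list alone (list adjusted p = 0.890). The remodeller gene Smarcad1 on chromosome 6 rose from 418 to 629 CPM, a log2 change of 0.59 that was 0.12 and not called after centring. Of 19 DNA methylation genes 3 rose and 1 fell, or 4 and 5 adjusted over the list alone (0.959). Among them, Tet2 on chromosome 3 (adjusted p = 0.0050) was at 0.0704 and 0.0634 without control replicate 1 and 2, and Mbd4 on chromosome 6 (0.0469) at 0.307 and 0.177. Mbd4 was also at 0.0640 without clone 1 replicate 2 and at 0.0738 and 0.0709 without clone 2 replicate 1 and 2. Of 30 Polycomb genes 6 rose and 3 fell, or 8 and 4 adjusted over the list alone (0.842). Ezh2, the H3K27 methyltransferase, also on chromosome 6, rose from 193 to 276 CPM, with a log2 change of 0.52 that was 0.04 and not called after centring. In the core and naive pluripotency list 2 of 34 rose and 4 fell, with the same counts adjusted over the list alone (0.971). Nanog on chromosome 6 had 498 and 626 CPM in control and DKO (adjusted p = 0.0281, and 0.193 and 0.190 without control replicate 1 and 2), and its log2 change of 0.33 was -0.14 after centring. Of 22 formative and primed genes 1 rose and 2 fell, or 1 and 3 adjusted over the list alone (0.344). Among 32 paternally expressed imprinted genes 4 rose and 5 fell, or 4 and 7 adjusted over the list alone (0.363). Among 34 maternally expressed ones 2 rose and 2 fell, or 3 and 3 adjusted over the list alone (0.363). Centring also ended calls on chromosomes 3 and 6, where the log2 change went from 0.31 to -0.16 for Resf1, 0.35 to 0.17 for Tet2, 0.47 to -0.0064 for Mbd4, 0.53 to 0.057 for Aebp2 and 0.46 to -0.014 for Copg2. The changes of Tdgf1 on chromosome 9 and Sox3 on X stayed about as large (-0.28 to -0.26 and -1.47 to -1.42), while their adjusted p became 0.0719 and 0.0734. Values in brackets after the counts are adjusted p of the list test.

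Markers of differentiated lineages did not pass as lists either. For primitive endoderm 2 of 19 genes fell and the other 17 did not pass, also over the list alone (list adjusted p = 0.0743, and 0.0325 without control replicate 1). For trophectoderm 2 of 17 rose and 3 fell, or 4 and 5 adjusted over the list alone (0.726), with a median of -0.28 and a mean of 0.07. That median was -0.18 without control replicate 1, 0.09 without control replicate 2 and -0.15 without clone 2 replicate 1. For mesoderm and primitive streak 2 of 17 rose and 2 fell, or 3 and 5 adjusted over the list alone (0.363). The Nodal inhibitor gene Lefty2 fell from 194 ± 7.21 to 80.03 ± 26.2 CPM (SD, n = 2 and 4), with adjusted p = 0.0058, 0.0879 without control replicate 1 and 0.0662 without control replicate 2. For neuroectoderm 1 of 21 rose and 1 fell, or 1 and 2 adjusted over the list alone (0.497). Of 6 Hox genes 1 fell, also over the list alone (0.842). Of 23 collagens 2 rose and 3 fell, or 2 and 5 adjusted over the list alone (0.114). Of 18 serpins 2 fell, also over the list alone (0.315). Of 368 Zfp genes 4 rose and 7 fell, or 2 and 5 adjusted over the list alone (0.655), and the call on Zfp638 of chromosome 6 ended after centring (0.39, then -0.08). The 12 olfactory and 15 vomeronasal receptor genes had no call in edgeR over all genes or the list alone (0.842 for each). At unadjusted p under 0.05, 1 olfactory gene was lower, and 3 vomeronasal genes were higher and 2 lower. DESeq2 called 1 vomeronasal gene higher and no olfactory gene, and limma-voom called none of either.

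Housekeeping and stress lists held scattered calls. Of 49 cell cycle genes 3 rose and the other 46 did not pass, also over the list alone (list adjusted p = 0.411). The replication factor gene Mcm2 on chromosome 6 rose from 547 to 845 CPM, a log2 change of 0.63 that was 0.15 and not called after centring (adjusted p = 0.206). Of 26 lysosome and autophagy genes 4 rose, also over the list alone (0.0678, but 0.0125 outside chromosomes 3, 6 and Y, 0.0338 with chromosomes centred, 0.0339 without a filter on low counts and 0.0379 without clone 2 replicate 2), and the protease gene Ctsl rose from 170 to 265 CPM. Of 24 cholesterol synthesis genes 4 fell, or 6 with 2 higher adjusted over the list alone (0.257). Hmgcs1 fell from 432 to 299 CPM (adjusted p = 0.0024, and 0.0668 without control replicate 1). Of 27 genes of the unfolded protein and amino acid response 5 rose, or 5 with 1 lower adjusted over the list alone (0.698). The asparagine synthetase gene Asns on chromosome 6 rose from 544 to 834 CPM, a call that ended after centring, with a log2 change of 0.62 and then 0.14, as did those of Mthfd2 (0.39, then -0.084) and Pdia4 (0.40, then -0.069) on the same chromosome. After centring and outside chromosomes 3, 6 and Y the test of this list pointed down (0.592 and 0.675). Centring also ended the calls of Gabarapl1 (0.93, then 0.45), Rpl32 (0.82, then 0.34) and Rps4l (0.44, then -0.036) on chromosome 6. It ended those of Cdc25c on 18 (0.43, then 0.37, adjusted p = 0.0537) and Fdft1 on 14 (-0.34, then -0.23, adjusted p = 0.0678) as well. Of 30 interferon response genes 3 rose and 1 fell, or 3 and 3 adjusted over the list alone (0.842). Of 85 cytosolic ribosomal protein genes 3 rose and the other 82 did not pass, also over the list alone (0.369). None of 34 p53 targets (0.715) or 18 immediate early genes (0.0892, but 0.0244 without control replicate 1 and 0.02 without clone 1 replicate 2) passed in edgeR, over all genes or the list alone. At unadjusted p under 0.05, 1 p53 target was higher and 1 lower, and 1 immediate early gene was higher and 6 lower. DESeq2 called 1 p53 target higher and no immediate early gene, and limma-voom called none. The median, the mean and the test did not share a sign for interferon, unfolded protein, Polycomb, pluripotency and olfactory genes.

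Each clone was then compared with the control on its own. In clone 1 1298 genes rose and 955 fell (57.6% higher), and outside chromosomes 3, 6 and Y 661 rose and 916 fell (41.9% higher). In clone 2 1165 rose and 1046 fell (52.7% higher), and outside those chromosomes 659 rose and 992 fell (39.9% higher). The 2-cell-like list had 23 genes lower in clone 1 and 28 in clone 2, with medians of -0.98 and -1.48. The Oosp, Obox and Pramel families had 16 and 14 genes lower, with medians of -1.01 and -1.31. With an estimated correlation the 2-cell-like list had adjusted p = 0.0543 in clone 1 and 0.0270 in clone 2, and the Oosp, Obox and Pramel families had adjusted p = 0.0591 and 0.0924. Of 34 p53 targets 7 rose and 1 fell in clone 1 (median 0.13, list adjusted p = 0.0260, adjusted p = 0.379 with an estimated correlation), while 13 fell in clone 2 (median -0.24, list adjusted p = 7.5e-06, adjusted p = 0.0924 with an estimated correlation). In both clones 711 genes rose and 470 fell, 12 were called in opposite directions, and independent lists of these sizes would share 102 and 67.6. Outside chromosomes 3, 6 and Y 285 rose and 449 fell in both. Unchanged groups simulated against shared controls gave means of 0.70 and 0.65 over 20 draws. These draws held no difference between clones, so they cannot show how many shared calls a trait of the control clone would give. Across genes the changes of the clones correlated at 0.626, against a simulated mean of 0.473 that the shared controls alone give, and genes are not independent replicates. In clone 1 the counts were 827 and 551 without control replicate 1, 590 lower without control replicate 2, and 797 and 495 without clone 1 replicate 1. In clone 2 the lower count was 693 and 596 without control replicate 1 and 2, and the counts were 682 and 526 without clone 2 replicate 1 and 656 and 467 without clone 2 replicate 2. The 470 genes lower in both clones became 288 and 295 without control replicate 1 and 2, 291 without clone 1 replicate 1, and 304 and 276 without clone 2 replicate 1 and 2.

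The clones also differed from each other. A2m, the protease inhibitor alpha-2-macroglobulin, stood at 3.59 CPM in clone 1 and 26.2 CPM in clone 2 (log2 difference 2.87, adjusted p = 8.2e-07). Ddr2, a collagen receptor, was higher in clone 2 by 1.63, and Fstl5 and the annexin gene Anxa3 were lower by -2.74 and -2.20. The maternally expressed RNAs Rian and Mirg of the imprinted Dlk1-Dio3 region on chromosome 12 were lower in clone 2. Rian stood at 226 CPM in the control, 239 in clone 1 and 64.3 in clone 2 (log2 difference -1.89, adjusted p = 3.4e-07), and Mirg at 17.5, 19.03 and 4.69 CPM. Meg3 of the same region, chosen after its values were seen, stood at 34.1, 32.4 and 10.9 CPM (log2 difference -1.57, adjusted p = 1.0e-04). Of 34 p53 targets 20 were lower in clone 2 than in clone 1, with a median of -0.43 (list adjusted p = 1.4e-22, and adjusted p = 0.0457 with an estimated correlation). Plk2, a kinase gene, stood at 90.8 CPM in clone 1 and 58.1 in clone 2, and Pmaip1, a gene of apoptosis, at 317 and 225 CPM. In all, 373 genes were higher and 557 lower in clone 2 (40.1% higher), and outside chromosomes 3, 6 and Y 328 were higher and 416 lower (44.1%). The counts were 156 and 238 without clone 1 replicate 1, 242 and 338 without clone 1 replicate 2, 115 and 155 without clone 2 replicate 1, and 128 and 166 without clone 2 replicate 2.

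**Figure D5:**
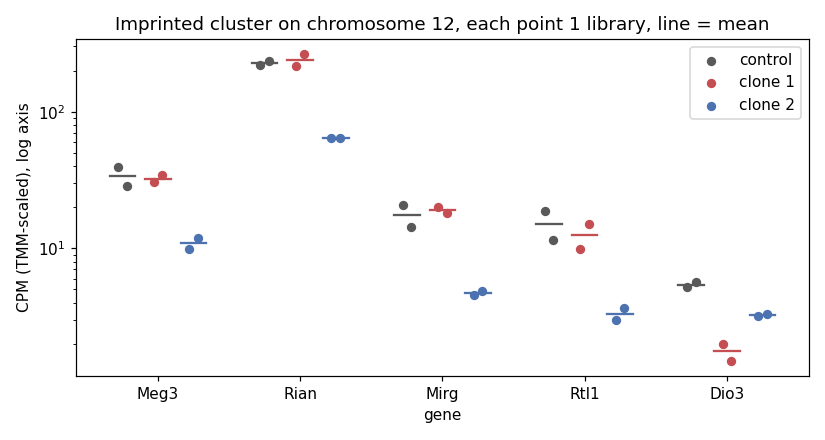
Expression of Meg3, Rian, Mirg, Rtl1 and Dio3 in CPM (vertical axis, log scale) in the control and both DKO clones, where each point is 1 library and each line the mean of 2. Rian stands at 226 CPM in the control, 239 in clone 1 and 64.3 in clone 2, and Rtl1 counts may include the antisense maternal transcript.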

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

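Tests chosen only after the result was seen were that of copy loss in the control, the split of chromosome 6 by control expression, the fit with centred chromosomes and those on the 2-cell-like genes. The other tests on chromosome 6 and on the imprinted region of chromosome 12 were written for patterns already seen in the data. The genes and lists given first differed between clone 2 and clone 1 by the test of the difference itself, and values are log2 changes of clone 2 minus clone 1 unless stated otherwise. The design names no biological difference between the clones.

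In total 373 genes were higher and 557 lower in clone 2 than in clone 1. Among genes higher in DKO than in control, the differences were -2.74 for Fstl5, -0.32 for Selenoi, -0.81 for Dcdc2a, -1.45 for Clec2f, -0.45 for Nrp2 and 0.60 for Trh. The call of Clec2f against control (adjusted p = 0.0455) ended after centring (0.144, with a log2 change of 1.92 before and 1.46 after), without control replicate 1 and 2 (0.145 and 0.327) and without clone 1 replicate 1 and 2 (0.0757 and 0.0745). Among genes lower in DKO, they were 1.81 for Usp26, -1.24 for Acta2, 1.07 for Pla2g1b and -0.84 for Bglap3, and the call of Pla2g1b against control ended without control replicate 1 and 2 (0.0525 and 0.0527). With Usp26, the genes that the rule names as higher in clone 2, at an average of 2 CPM or more, were A2m at 2.87, Slc16a3 at 1.97, Trim43a at 1.84, Vax2os at 1.76 and Ddr2 at 1.63, and Anxa3 was lower at -2.20. Among list members, the differences were -0.34 for Nr5a2, 0.85 for Lamb1, 0.83 for Lefty2, -0.52 for Bmp4, 0.54 for Nkx1-2 and 0.93 for Lefty1. They were -0.65 for Plk2, -0.50 for Pmaip1, -0.36 for Mdm2, -0.60 for Klf6, -0.76 for Rpl39l, 0.59 for Rpl32l and -1.46 for Col6a5. Leaving out 1 library ended part of these calls, and the difference of Slc16a3 was 1.02 without clone 2 replicate 1 and that of Rpl32l 0.32 without clone 2 replicate 2. Without clone 2 replicate 1 the adjusted p was 0.176 for Selenoi, 0.0708 for Dcdc2a, 0.0619 for Nrp2, 0.122 for Acta2, 0.213 for Slc16a3, 0.0655 for Nr5a2, 0.0631 for Bmp4, 0.245 for Nkx1-2, 0.160 for Lefty1, 0.0620 for Mdm2 and 0.164 for Col6a5. Without clone 2 replicate 2 it was 0.265 for Selenoi, 0.0588 for Clec2f, 0.0683 for Nrp2, 0.0840 for Acta2, 0.0514 for Pla2g1b, 0.0948 for Nr5a2, 0.118 for Nkx1-2, 0.0539 for Mdm2, 0.0536 for Rpl39l and 0.456 for Rpl32l. Without clone 1 replicate 1 it was 0.160 for Selenoi, 0.0630 for Acta2, 0.0883 for Slc16a3, 0.235 for Nkx1-2 and 0.193 for Rpl32l. Without clone 1 replicate 2 it was 0.141 for Selenoi, 0.0512 for Dcdc2a, 0.0670 for Acta2, 0.0619 for Slc16a3, 0.0748 for Nkx1-2, 0.109 for Lefty1, 0.109 for Rpl32l and 0.133 for Col6a5. Without control replicate 1 and 2 it was 0.0519 and 0.0558 for Nkx1-2 and 0.0617 and 0.0627 for Rpl32l. The counts without 1 library were 156 and 238 without clone 1 replicate 1, 242 and 338 without clone 1 replicate 2, 115 and 155 without clone 2 replicate 1 and 128 and 166 without clone 2 replicate 2.

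As lists, 8 differed between the clones. The medians were -0.32 for 2-cell-like genes, 0.12 for germline genes, -0.034 for maternally expressed imprinted genes, -0.35 for neuroectoderm and neuronal genes, -0.43 for p53 targets, 0.19 for glycolysis and hypoxia genes, -0.24 for immediate early genes and 0.17 for replication-dependent histone genes. With an estimated correlation adjusted p = 0.0457 for the p53 targets, while the other 7 lists ranged from adjusted p = 0.207 to 0.629 and did not pass.

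Chromosome 6 genes were higher in both clones than in the control. Extra copies of the chromosome in both clones predict that genes of every expression level rise, and with its genes split by expression into tertiles the lowest median shift in either clone was 0.26, or 0.33 with tertiles by control expression alone. Release of silent or weakly expressed genes is argued against by the most expressed tertile, whose median shift was 0.465 in clone 1 and 0.526 in clone 2. With tertiles by control expression alone it was 0.460 and 0.524. Loss of 1 of 2 copies in every control cell would give a shift of 1, and 3 copies against 2 in every DKO cell 0.585. Both lie above the 0.48 seen, the first by more. No value here decides on copy loss in all or part of the control cells. The shift is relative to that clone, and no diploid reference library was used here. Extra copies in both clones or a loss of copies in the control therefore remain candidate explanations, and the effect of the knockout itself cannot be separated from them with 1 control clone.

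The 2-cell-like genes were lower in both clones. With an estimated correlation the list test gave adjusted p = 0.12 for DKO, 0.0543 for clone 1 and 0.0270 for clone 2. Reads moving between near-identical copies are argued against by summed counts, since over the Zscan4 and Usp17l families the smallest fall was -1.22, while the summed Pramel family was closer to the control, at -0.79 in clone 1 and -0.78 in clone 2. Copy changes of chromosomes are argued against by the 34 genes outside chromosomes 3, 6, 14 and Y, with a median of -1.24. Fewer 2-cell-like cells in both clones stays open: at least 85.4% of the list lay below 0 in each clone, but this restates the fall, and lower expression in each such cell would give the same values in bulk RNA. With 1 control clone, a trait of that clone stays open as well.

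Meg3 was lower in clone 2 than in clone 1 by -1.57, Rian by -1.89, Mirg by -2.02, Mir3072, which lies inside Mirg, by -2.14 and Rtl1 by -1.90. Loss of a copy of distal chromosome 12 is argued against by the 70 protein-coding genes within 5 Mb of the cluster, whose median difference was -0.062 (SD 0.344). A switch of the maternal copy to the paternal pattern could lower these RNAs, but the gene that would show it, Dlk1, had at most 10 reads in a library and was not tested, so this stays open. Rtl1 overlaps an antisense maternal transcript, so its count is uncertain. Dio3, chosen after its values were seen as was Meg3, was below the control in both clones, by -1.62 in clone 1 and -0.73 in clone 2, so its difference of 0.89 (adjusted p = 0.0334) came with a deeper fall in clone 1.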

How the results depend on the processing

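The counts and list tests outside chromosomes 3, 6 and Y and the fits with each chromosome centred were the only tests here chosen after the result was seen. The limit of 40 Mb on chromosome 14, which centring also used, was not fixed beforehand either. For DKO against control the mean of the 3-group fit gave 1379 higher and 1249 lower, counts summed per clone 0 and 2 in edgeR (883 and 742 at unadjusted p under 0.05), clone 1 alone 1176 and 847, clone 2 alone 1185 and 1098, a change of at least 2-fold 83 and 180, and adjusted p under 0.01 340 and 191. The 3-group and single-clone fits use another estimate of spread, summed counts leave 1 residual degree of freedom, and the 2-fold and 0.01 settings are stricter by construction. Outside chromosomes 3, 6 and Y and after centring, the higher counts were 305 and 335 for DKO, 661 and 731 for clone 1, 659 and 744 for clone 2, and 285 and 327 in both clones, since genes of chromosomes 3, 6 and Y are removed together or every chromosome is centred. Without a filter 644 genes were higher in clone 2 than in clone 1; the cause was not tested. Lists called with an estimated correlation were 0 higher and 1 lower against 3 and 6, and fry, which tests whether a list moves one way and not against other genes, called 1 higher and 9 lower. Fry left histones, glycolysis and gamma protocadherins at 0.188, 0.205 and 0.136, and limma-voom put primitive endoderm, lysosome, immediate early and collagen genes at 0.0493, and without a filter lysosome genes were at 0.0339; the cause was not tested. The chromosome 6 shift was 0.4140 without a filter and 0.4153 with DESeq2 in clone 1, and 0.4891 and 0.4908 in clone 2. That of chromosome 3 in clone 1 was 0.2583 and 0.2668, and that of chromosome 14 from 40 Mb in clone 2 was -0.1984 without a filter, -0.1846 at 2 CPM and -0.1987 with limma-voom; the cause was not tested. With chromosomes centred Resf1 reversed to -0.16, Mbd4 to -0.0064, Nanog to -0.14, Copg2 to -0.014, Hk2 to -0.13, Mthfd2 to -0.084, Pdia4 to -0.069, Zfp638 to -0.08 and Rps4l to -0.036, since the shift of their chromosome is removed.

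Leaving out each library in turn gave 158 to 715 higher and 88 to 482 lower for DKO, 797 to 1198 and 495 to 853 for clone 1, 656 to 1197 and 467 to 1105 for clone 2, 115 to 377 and 155 to 557 between the clones, and 480 to 615 and 276 to 384 in both. It gave 2 to 4 lists higher and 3 to 8 lower. The shifts ranged from 0.4349 to 0.4574 for chromosome 6 in clone 1, 0.4962 to 0.5156 in clone 2, 0.2580 to 0.2969 for chromosome 3 in clone 1 and -0.2061 to -0.1932 for chromosome 14 from 40 Mb in clone 2. Where 1 library of a group is left, it is assumed to vary like the other groups. A replicate block gave 555 and 373 for DKO, although replicate numbers did not pair libraries (correlations 0.028, -0.083 and 0.026). For DKO, RLE gave 751 and 531, library size 776 and 502, no filter 833 and 658, 2 CPM 708 and 502, DESeq2 951 and 607 and limma-voom 745 and 611, all within 1.5 times the reported counts. Of the values of single named genes under the alternatives 2209 kept direction and side of the threshold, 412 lost the call and 9 reversed. Only genes called in the main fits entered this tally, so no call could be gained. The kept values include 107 from the setting outside chromosomes 3, 6 and Y, which re-used the main fits and so could not differ. Genes under the filter on low counts were not tested at this depth, among them Dlk1 with at most 10 reads in a library.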

Other observations

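The splits by control expression and by the midpoint of the group means were the only tests here chosen after the result was seen, and the genes named here were chosen after their values were seen, except Klf6. Between the clones, members of further lists differed beyond the imprinted region, although with an estimated correlation the lists gave adjusted p = 0.493 for neuronal genes, 0.576 for glycolysis and 0.576 for immediate early genes, and only the p53 targets passed (0.0457). Among neuronal genes, the neurofilament genes Nefm and Nefl stood at 134 and 132 CPM in clone 1 and at 80.1 and 84.2 CPM in clone 2, against 73.3 and 87.0 CPM in the control. Vim, an intermediate filament gene, stood at 648 CPM in clone 1 and 448 CPM in clone 2. Nefm and Nefl lie on chromosome 14, where clone 2 was lower as a block from 40 Mb. Among glycolysis genes, Pgk1 stood at 116 CPM in clone 1 and 190 CPM in clone 2, and Tpi1 at 66.5 and 103 CPM. Among immediate early genes, Klf6 stood at 80.4 and 53.2 CPM and Btg2, also a member of the p53 target list, at 47.3 and 31.7 CPM. Grb10, a maternally expressed imprinted gene on chromosome 11, stood at 62.6 CPM in the control, 49.2 CPM in clone 1 and 23.1 CPM in clone 2. The p53 targets Perp, Aen and Zmat3 stood at 49.5, 99.2 and 79.3 CPM in clone 1 and at 25.98, 71.5 and 56.8 CPM in clone 2. Trp53 itself stood at 185 and 188 CPM, a log2 difference of 0.02 with adjusted p = 0.908.

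A pair of hypotheses about heterochromatin were tested, leaving out the chromosomes whose shifts had already been seen. If loss of HP1 alpha and beta raised genes near pericentric heterochromatin, genes within 15 Mb of the chromosome start would be higher than the others. Outside chromosomes 3, 6, 14 and Y the median of 1164 such genes minus that of 11668 others was -0.01 in each clone, so the prediction was not met. The difference was -0.0083 (bootstrap SE 0.0079) in clone 1 and -0.0103 (bootstrap SE 0.0097) in clone 2. These SE came from resampling genes, which are not independent replicates. If weakly expressed genes were released, most called genes in the lowest tertile by expression would be higher. Of the called genes in that tertile outside the same chromosomes 41 rose and 182 fell, so 18.4% were higher (95% interval 13.5 to 24.1%), against 43.1% in the middle tertile and 48.3% in the highest. This split used the mean of all libraries, 4 of 6 of them DKO, so genes that fell were drawn into the lowest tertile. Split by control expression alone 57 rose and 130 fell in the lowest tertile, so 30.5% were higher (24.0 to 37.6%), and split by the midpoint of the group means 21.2% were. By each split the prediction was not met.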
